A study of Homo sapiens with 4 samples.

How the data were processed

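The series measured N6-methyladenosine (m6A), a methyl mark on adenosine in RNA, by immunoprecipitation and sequencing (MeRIP-seq) in MDA-MB-231, a triple-negative breast cancer cell line. Per the labels' protocols, RNA was broken into short fragments, a part was kept as input, and the rest was pulled down with an antibody against m6A. Libraries were stranded, carried a unique molecular identifier (UMI), had ribosomal RNA sequences removed, and were sequenced in pairs. The labels name 4 samples in 2 groups, m6A-IP and input, with 2 replicates each. Peak lists of the 2 m6A-IP replicates were used here; the input libraries entered only as columns of those lists. Nothing in the labels says that the replicates came from separate cultures, so differences between them may measure technical spread.

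Per the submitters' processing notes, the authors used bcl2fastq and TopHat2 with the human genome build GRCh38; no versions are given. The peak caller, the gene annotation release and the treatment of the UMIs are not given in the sources used here. Peaks were called per replicate, not on pooled samples, since each list has IP and input columns of its own. The labels do not say which input sample stands behind which list, and each list's input column was used only within that list. Per the file headers, each peak has a deposited log2 fold change and a p-value from the authors' caller, IP and input values that the headers call normalized, IP and input RPKM, and a depth signal at the peak. The deposited normalized values are whole numbers of unstated origin and are treated as a score, called the IP value and the input value here. In every peak the deposited RPKM equalled this value divided by the peak length in kilobases and by a fixed total, within 0.01 RPKM or 0.1 percent. The implied totals, rounded, were 18700000 (IP) and 14900000 (input) for replicate 1, and 19100000 and 11900000 for replicate 2. The authors' log2 fold equalled log2 of (IP RPKM + 1) over (input RPKM + 1), which understates the enrichment of weak peaks. Both lists hold only peaks with a log2 fold of at least 1 and a p-value below 0.01, so a gene without a peak has no measured value here. Region, gene symbol and the shares of a peak in each part of a transcript are the authors' annotation, per the file headers. In 480 peaks of replicate 1 and 498 of replicate 2 the lists give 2 different gene identifiers; the identifier that goes with the symbol was used, and the transcript part may then refer to the other gene.

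Coordinates are 1-based on GRCh38, as deposited. A peak was called shared when it overlapped a peak of the other replicate by at least 1 base on the same strand. Best one-to-one pairs were taken by overlap, and their folds are given as mean ± SD of the log2 folds of the 2 replicates. Shares have exact Clopper-Pearson intervals at the 95% level, which cover counting error only. The share of shared peaks was set against 100 random placements of each replicate 2 peak within the span of its own gene, since exon coordinates were not used here; 496 peaks of genes without a span were left out. Correlations were computed across peaks, which are not independent replicates, with intervals from 1000 bootstrap resamples over genes. The balance of peaks across the stop and the start codon was tested with a two-sided exact binomial test.

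For gene lists, the share of members with a shared sense-strand peak was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 17 lists. Symbols were matched to a RefSeq gene table of GRCh38.p14 by symbol or unambiguous synonym; 93.2% of the symbols in the replicate 1 list and 93.4% of those in the replicate 2 list matched. TAZ and NDUFA4 had no unambiguous match, and MALAT1 and NEAT1, being noncoding, stayed out of the test. Expression per gene was not analysed here, so a gene without a peak may lack m6A or may not be expressed. As an alternative, 10000 random lists were matched to each gene list by deciles of gene span.

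Genes were named by a rule set before the data were examined. It takes the 10 protein-coding genes with the highest mean log2 fold of their best shared peak, the 5 genes with the most shared peaks, SLIT2, IGF2BP3 and ROBO1, up to 4 members of each list with the highest mean log2 fold, and the 3 protein-coding genes per replicate with the highest fold among peaks not shared. Other genes named were chosen after their values were seen, and a member that the rule takes is not reported here. The alternatives were a p-value of at most 0.001, a fold of at least 4, a reciprocal overlap of 50%, a background of genes with a peak in either list, span-matched lists and each replicate alone. After seeing the data, exonic or intronic peaks alone, an IP value of at least 100, a pseudocount of 0.1 RPKM and a minimum of 10% of a peak on each side of the stop codon were added. The search for the DRACH motif and placements around the stop codon in transcript coordinates were not run, because genome sequence and transcript models were not used here; the authors' transcript parts took their place. The overlap, pairing and list tests were checked on simulated data, where all 6000 planted shared peaks were recovered. Of 100 simulated gene lists with no effect 1 had p under 0.05. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.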

Results

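MDA-MB-231 cells, an aggressive line of triple-negative breast cancer with mesenchymal features, were profiled for m6A in RNA by antibody pull-down. The title of the series links the m6A reader IGF2BP3 to repression of SLIT2, a secreted guidance protein that signals through ROBO receptors. The comparison the design holds is that of m6A-IP with input in each of 2 replicates, and the question it answers is which transcripts, and which parts of them, were enriched by the antibody. The replicate 1 list held 11173 peaks and the replicate 2 list 10711. The implied library totals were about 18700000 and 19100000 for the IP and 14900000 and 11900000 for the input. The median peak had an IP RPKM of 9.40 against an input RPKM of 3.05 in replicate 1, and 10.46 against 3.42 in replicate 2. Folds below are mean ± SD of the log2 fold over both replicates (n = 2), on the scale of RPKM + 1.

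SLIT2 carried 3 peaks on the plus strand of chromosome 4 (GRCh38), each called in both replicates. The first lay wholly in the 5′ UTR, at 20252937–20253222 in replicate 1 and 20252278–20253223 in replicate 2. Its log2 fold was 1.31 ± 0.27, with an IP RPKM of 17.8 against an input RPKM of 5.62 in replicate 1 and 7.77 against 3.02 in replicate 2. The next, at 20253763–20253998 in replicate 1, lay 22% in the 5′ UTR and 76% in coding sequence and had a log2 fold of 1.34 ± 0.20. The third, at 20618768–20619608 in replicate 1, crossed from coding sequence (29%) into the 3′ UTR (71%) and had a log2 fold of 1.18 ± 0.19. That fold was 1.05 in replicate 1, near the lower limit of 1 in the lists, and 1.31 in replicate 2. Over all shared peaks the median log2 fold was 1.30 in replicate 1 and 1.36 in replicate 2. The authors' p-values of these 6 SLIT2 calls ranged from 1.16e-09 to 3.45e-05. IGF2BP3 itself had 1 shared peak, on the minus strand of chromosome 7 at 23414572–23415352 in replicate 1, in an exon annotated as noncoding. Its log2 fold was 1.19 ± 0.21, with 1.04 in replicate 1, also near the lower limit, and 1.34 in replicate 2. A weak intronic IGF2BP3 peak at 23359714–23359939, with an IP value of 10 and an input value of 0, was called in replicate 1 and not in replicate 2. ROBO1, a receptor of SLIT2, had no peak in either list.

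**Figure D1:**
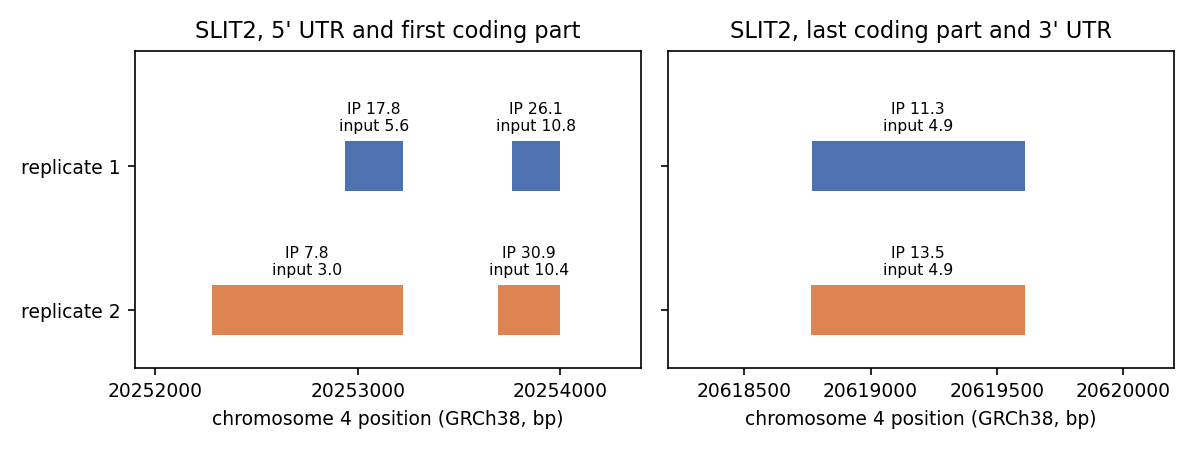
Peaks of SLIT2 on chromosome 4 (GRCh38 position in bp on the x axis), one bar per peak and replicate, with the IP and input RPKM of the peak above each bar. All 3 peaks are present in both replicates; the first is longer in replicate 2, where its IP RPKM is 7.77 against 17.8 in replicate 1.

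Exons held the largest part of the peaks, 47.9% (95% interval 46.9–48.8) in replicate 1 and 51.1% (50.1–52.0) in replicate 2. Introns held 39.4% and 37.1%, the strand opposite to a gene 4.82% and 4.54%, and sequence between genes 7.89% and 7.29%. Of the replicate 1 peaks, 49.2% (48.2–50.1) overlapped a peak of replicate 2, and of the replicate 2 peaks 51.1% (50.2–52.1) overlapped a peak of replicate 1. Exonic peaks of replicate 1 were shared in 65.3% (64.0–66.6) and intronic peaks in 33.4% (32.0–34.8). Sharing was more frequent in deeper peaks: in replicate 1 it was 12.9% (11.7–14.2) at IP values of 10 to 33 and 82.9% (81.4–84.3) at values of 157 and above. Replicate 2 peaks on the sense strand of a gene were shared in 52.9%, against a mean of 4.65% and a highest value of 5.17% in 100 random placements within their genes. The p of 0.0099 is the smallest these placements can give. The placements covered the whole gene span, introns included, so any calls confined to the covered parts of a gene would exceed them. The gap therefore does not separate recurring m6A sites from recurring coverage. By gene, 74.7% of the protein-coding genes with a peak in replicate 1 also had one in replicate 2, and 3268 protein-coding genes had a shared peak.

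**Figure D2:**
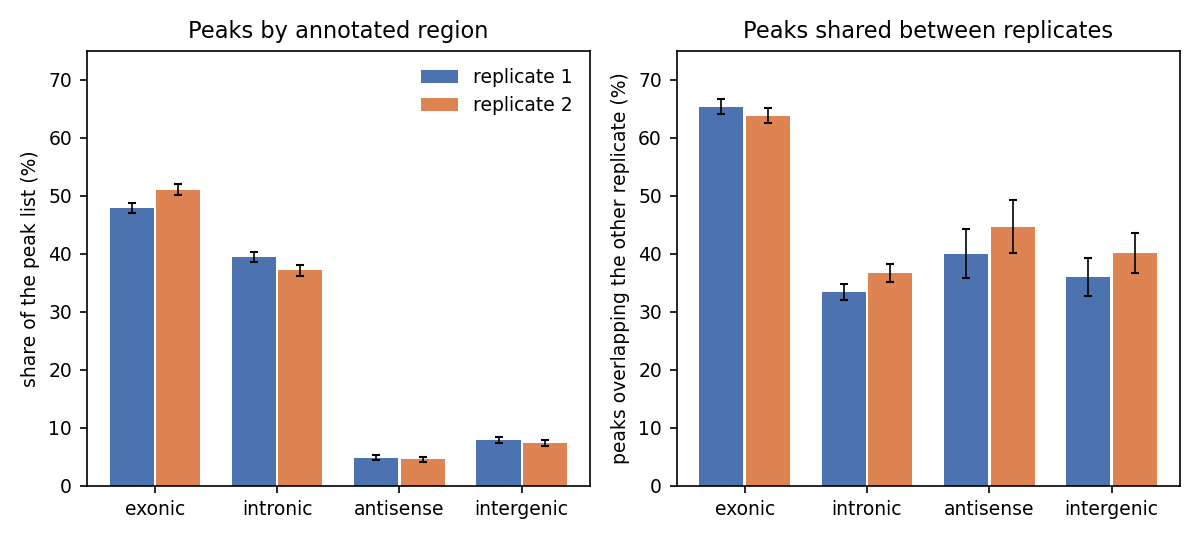
Left, share of each peak list by annotated region (percent); right, share of the peaks in each region that overlap a peak of the other replicate (percent), with exact 95% intervals as error bars. Exonic peaks make up 47.9% and 51.1% of the lists and are shared most often, in 65.3% and 63.8%.

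**Figure D3:**
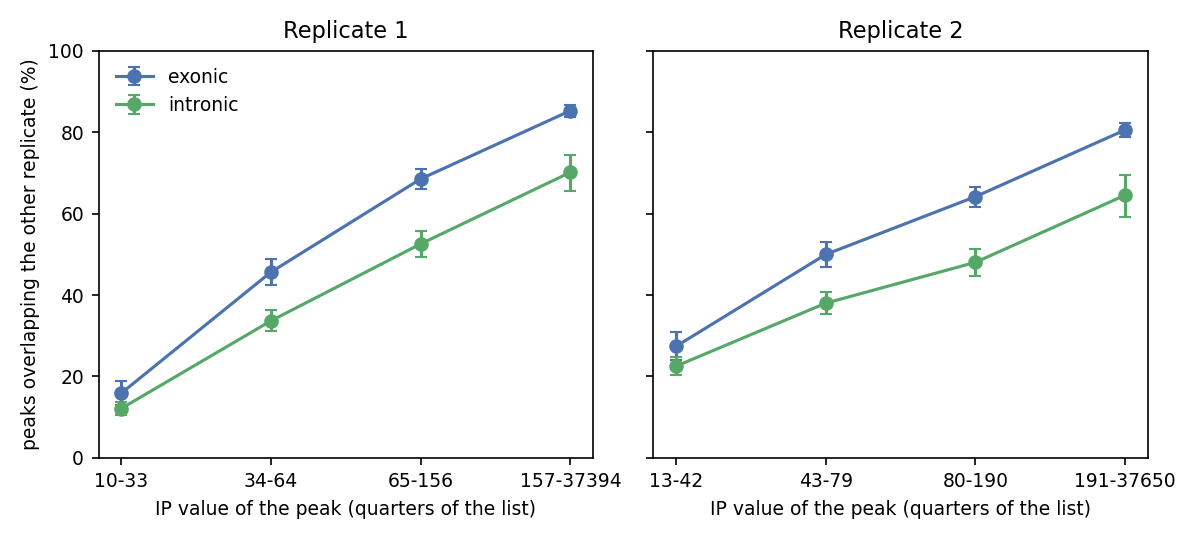
Share of exonic and intronic peaks that overlap a peak of the other replicate (percent, y axis) in 4 classes of IP value (x axis), with exact 95% intervals, for replicate 1 (left) and replicate 2 (right). Exonic peaks of the deepest class are shared in 85.3% in replicate 1 and intronic peaks of that class in 70.1%.

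Over 5432 one-to-one pairs of shared peaks, the log2 folds of the replicates correlated with Pearson's r of 0.497 (0.471–0.523) and Spearman's rho of 0.465. Both folds of a pair had passed the lower limit of the lists, which narrows their range. IP RPKM, as log2 of RPKM + 1, correlated more closely, with r of 0.970 (0.967–0.972). Input RPKM on that scale did so nearly as closely, with 0.965 (0.963–0.968), so the r of IP RPKM does not measure agreement of the enrichment. The fold was higher in replicate 2 in 59.0% of the pairs, by a median log2 difference of 0.05, against an SD between replicates of 0.21. The highest mean folds belonged mostly to short peaks of low IP value. An intronic peak of AKAP1, a scaffold protein of the outer mitochondrial membrane, had a log2 fold of 2.97 ± 0.13, at 57100286–57100461 on chromosome 17. A 3′ UTR peak of NMT1, an N-myristoyltransferase, reached 2.89 ± 0.45 and an intronic peak of ALMS1, a centrosomal protein, 2.82 ± 0.25. NEIL1, a DNA glycosylase of base excision repair, followed at 2.69 ± 0.03. WIPI2, an autophagy protein, had the deepest of these 10 peaks, across the stop codon on chromosome 7 at 5230834–5231069, with IP values of 170 and 194 against input values of 21 and 16 and a log2 fold of 2.60 ± 0.13. The remaining members of this top group were FAM117B (2.57 ± 0.46), RAD51B (2.54 ± 0.22, intronic), MYORG (2.52 ± 0.34), SPACA6 (2.51 ± 0.33) and ITCH (2.49 ± 0.32, intronic). Input values in these peaks, WIPI2 apart, were 5 or less, and with a pseudocount of 0.1 RPKM 4 of the 10 genes stayed among the top 10.

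GMDS-DT, a long noncoding RNA, TGFB1, which encodes a growth factor of the TGF-β family, and WFDC10B each had 7 shared peaks. Of the 5 genes with 6 each, the rule took LINC01411 and the transcription factor gene NFIC, with ties in symbol order. The best shared peak of GMDS-DT lay in a noncoding exon on chromosome 6 at 2272442–2273162 and had a log2 fold of 1.70 ± 0.35. Those of TGFB1 (1.73 ± 0.56), WFDC10B (2.26 ± 1.09), LINC01411 (1.64 ± 0.22) and NFIC (2.07 ± 0.91) were intronic. For WFDC10B and NFIC the replicates differed widely, with log2 folds of 1.49 and 3.03 for WFDC10B and 1.43 and 2.72 for NFIC. Among peaks called in a single replicate, the highest folds in replicate 1 were those of COL6A1, a collagen VI chain (log2 fold 3.28), ZNF316 (3.26) and PDCD4 (3.24). In replicate 2 they were those of HEATR1 (3.35), CLNS1A (3.09) and PSME3IP1 (2.97), all intronic. The IP values of these 6 peaks were 16 to 31 and their input values 0 or 1.

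The position of m6A along messenger RNA was taken from 2983 shared exonic peaks of protein-coding transcripts. Coding sequence was the main part in 61.0% (59.3–62.8), the 3′ UTR in 30.5% (28.9–32.2) and the 5′ UTR in 8.41% (7.44–9.47). Peaks that crossed the stop codon, from coding sequence into the 3′ UTR, numbered 833 (27.9%, 26.3–29.6), and those that crossed from the 5′ UTR into coding sequence 220 (7.38%, 6.46–8.37). The ratio was 3.79 (exact binomial test, two-sided, p = 2.1e-84). That test takes equal numbers of both kinds as its null and treats peaks as independent. It does not allow for the lengths of the transcript parts or for coverage along them, so it does not measure a preference of m6A for the stop codon. In the full lists the ratio was 3.22 in replicate 1 and 3.40 in replicate 2, and among the peaks not shared it was 2.29 and 2.80. SOS1, PDPK1, PIK3CA, NEO1, EGR1, JUN and IER5 were among the named genes whose best peak crossed the stop codon. Peaks mainly in the 3′ UTR had a median log2 fold of 1.36, those mainly in coding sequence 1.30 and those mainly in the 5′ UTR 1.35; these differences were not tested.

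Of all protein-coding genes, 16.3% had a shared sense-strand peak, which is the level against which the gene lists stand. Chromatin regulators had the highest share, with 26 of 38 members (68.4%, 51.3–82.5; odds ratio 11.2, adjusted p = 1.8e-11, Fisher's exact test). By the peaks of a single replicate the odds ratio was 19.1 without replicate 2 and 16.1 without replicate 1. Their median gene span was 93.7 kb. Against random lists matched on gene span they had 2.80 times the matched number of members (adjusted permutation p = 0.0034), a ratio of counts and not an odds ratio. Immediate early genes had 3.65 times and m6A writers 3.43 times the matched number. The matched shares were 24.4% for chromatin regulators, 8.80% for immediate early genes and 17.0% for m6A writers. The highest possible ratio therefore differed, and these ratios do not rank the lists. ARID1A and ARID1B, subunits of the SWI/SNF remodelling complex, had log2 folds of 1.87 ± 0.09 and 2.10 ± 0.66 in their best shared peaks, both mainly coding. The CHD7 remodeller had a coding peak at 1.88 ± 0.08, on chromosome 8 at 60865668–60865908. ARID1A carried 5 shared peaks and CHD7 4. The best peak of CREBBP, a histone acetyltransferase, was intronic and weak (1.74 ± 0.26, input value 0 in both replicates).

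The list of m6A writers was taken broadly, as methyltransferases of the N6 position of adenosine in RNA and their partners. Of its 12 members 7 had a shared peak (58.3%, 27.7–84.8; odds ratio 7.21, adjusted p = 0.0042, Fisher's exact test). The odds ratio was 4.03 without replicate 2 and 9.01 without replicate 1. ZC3H13, a subunit of the main m6A methyltransferase complex, had 5 shared peaks, the best of them coding, on chromosome 13 at 45985479–45985769, with IP RPKM of 296 and 267 against input RPKM of 90.1 and 77.2 and a log2 fold of 1.74 ± 0.05. WTAP followed at 1.74 ± 0.03, METTL16 at 1.48 ± 0.01 and METTL14 at 1.28 ± 0.07. METTL3, the catalytic subunit, had no peak in either list. Erasers and readers of m6A did not pass the test (6 of 18, adjusted p = 0.15, Fisher's exact test). With replicate 2 alone they did (adjusted p = 0.0035, Fisher's exact test). YTHDF2, a reader that promotes RNA decay, had a coding peak at 1.21 ± 0.09, FXR2 a 5′ UTR peak at 1.28 in replicate 1 and 1.11 in replicate 2, and HNRNPC an intronic peak at 1.37 ± 0.004. Of the CCR4-NOT deadenylase complex and its partners 4 of 17 had a shared peak (adjusted p = 0.54, Fisher's exact test), namely CNOT4 (1.54 in replicate 1 and 1.46 in replicate 2), CNOT2 (1.42 ± 0.04), TOB1 (1.27 ± 0.10) and TOB2 (1.16 ± 0.04).

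Genes of SLIT-ROBO signalling had a shared peak in 11 of 26 cases (42.3%, 23.4–63.1; odds ratio 3.78, adjusted p = 0.0042, Fisher's exact test). Their median gene span was 147 kb, against 24.1 kb for all protein-coding genes, and the call was lost against 10000 random lists matched on gene span (adjusted permutation p = 0.16), with 1.67 times the matched number of members. Besides SLIT2, the list held SOS1, a Ras and Rac exchange factor (1.84 ± 0.16), and the adaptor NCK1 (1.79 ± 0.31). It also held SRGAP1, a GTPase-activating protein that binds ROBO1 (1.53 ± 0.06, intronic), and MYO9B (1.35 ± 0.02, intronic). The ligands SLIT1 and SLIT3 had no peak in either list. Other axon guidance ligands and receptors had shared peaks in 18 of 36 cases (95% interval 32.9–67.1%; odds ratio 5.16, adjusted p = 2.4e-05, Fisher's exact test). Of these 18 genes, 15 had an exonic shared peak. The median gene span of this list was 103 kb, with 2.18 times the span-matched number of members (adjusted permutation p = 0.0034). By fold, intronic peaks led here, in EFNA5, an ephrin (2.00 ± 0.68), NRP1, a co-receptor of semaphorins and VEGF (1.99 ± 0.85), and SEMA4D (1.76 ± 0.01). NEO1, a netrin receptor, had a peak across the stop codon at 1.67 ± 0.21.

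The PI3K-AKT and MEK-ERK pathways had 15 of 36 members with a shared peak (41.7%, 25.5–59.2; odds ratio 3.68, adjusted p = 0.0015, Fisher's exact test). RPTOR, the scaffold of the mTORC1 kinase, had a 3′ UTR peak at 2.04 ± 0.51, PDPK1, the kinase that activates AKT, a peak at 1.96 ± 0.11, and PIK3CA, a catalytic subunit of PI3K, a peak at 1.64 ± 0.13. The best peak of MAP2K1 was intronic (1.94 ± 0.10). Members of these pathways had a median gene span of 83.3 kb and 1.93 times the span-matched number (adjusted permutation p = 0.028). Mesenchymal and EMT genes had 11 of 26 (42.3%, 23.4–63.1; odds ratio 3.78, adjusted p = 0.0042, Fisher's exact test). Examples besides TGFB1 were CDH11, a mesenchymal cadherin (1.72 ± 0.07, intronic), TNC, a matrix glycoprotein (1.54 ± 0.13, coding), and ZEB2, a repressor of E-cadherin (1.48 ± 0.07, coding). The mesenchymal list had a median gene span of 38.7 kb and 2.28 times the span-matched number of members (adjusted permutation p = 0.024).

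Cytosolic ribosomal proteins were below the level of other genes, with 4 of 79 members (5.06%, 1.40–12.5; odds ratio 0.273, adjusted p = 0.0086, Fisher's exact test). Nuclear-encoded subunits of the respiratory chain were also below it, with 2 of 57 (3.51%, 0.428–12.1; odds ratio 0.186, adjusted p = 0.013, Fisher's exact test). Without replicate 1 their odds ratio was 0.287 and their share 8.77%, and without replicate 2 these were 0.216 and 7.02%. The median gene spans of the ribosomal and respiratory lists were 5.01 and 10.6 kb, and against span-matched random lists both calls were lost (adjusted permutation p = 0.42 and 0.14), with 0.588 and 0.306 times the matched number of members. The 4 ribosomal genes were RPS9 (2.12 ± 0.55, intronic), RPL37 (1.49 ± 0.19), RPL13 (1.42 ± 0.45) and RPS24 (1.16 ± 0.14). Those of the respiratory list, which takes in subunits of ATP synthase, were ATP5F1D, such a subunit (1.70 ± 0.15), and NDUFS1 (1.22 ± 0.16, intronic). All 8 calls, the higher and the lower ones, were lost when the background was restricted to genes with a peak in either list (adjusted p from 0.097 to 0.91, Fisher's exact test). That background holds 6326 protein-coding genes in place of 20056 and leaves out list members without any peak. It asks how often genes with a peak had a shared one, and no longer whether list members have peaks more often.

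**Figure D4:**
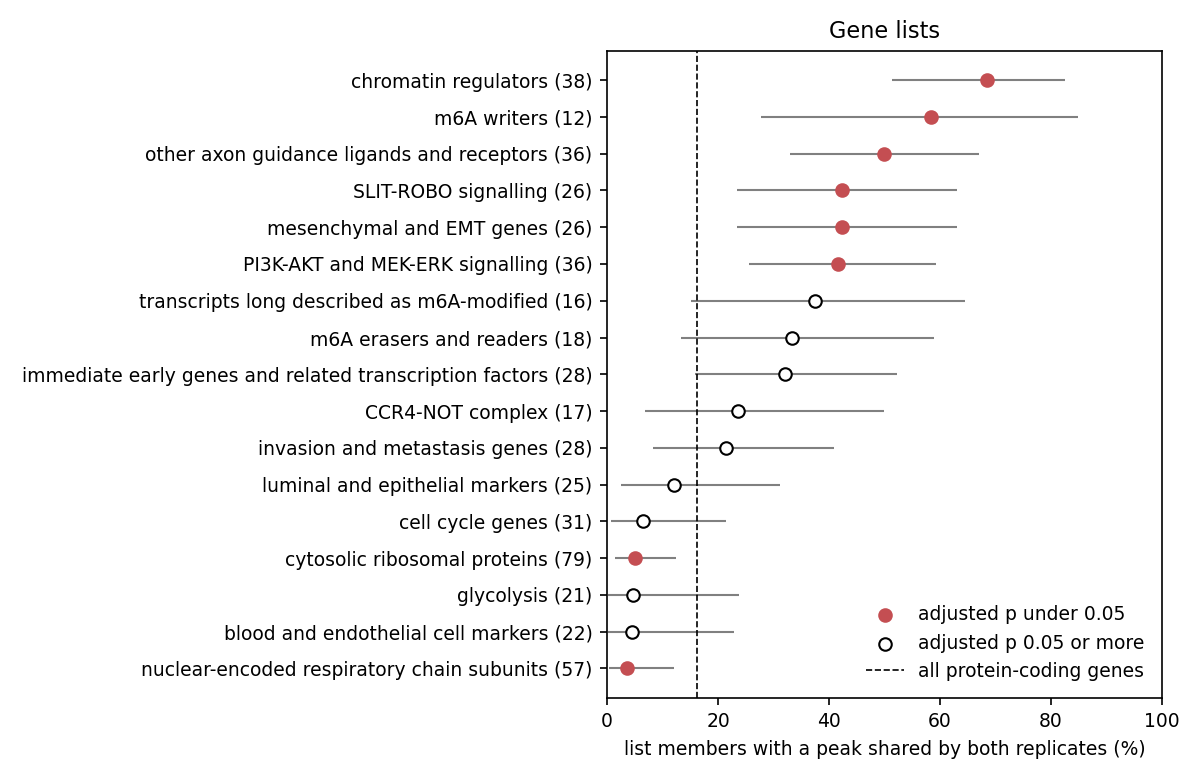
Share of the members of each gene list with a peak shared by both replicates (percent, x axis), with exact 95% intervals and the number of tested members in brackets; filled points have an adjusted p under 0.05 and the dashed line marks all protein-coding genes. Chromatin regulators (68.4%) and m6A writers (58.3%) lie highest, and respiratory chain subunits (3.51%) lowest.

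The other lists did not pass the test against all protein-coding genes. Immediate early genes and related transcription factors had 9 of 28 (adjusted p = 0.061, Fisher's exact test) and, with a median gene span of 4.89 kb, passed against span-matched random lists (adjusted permutation p = 0.0045). EGR1 had a peak across the stop codon at 2.24 ± 0.20, SOX4 a 3′ UTR peak at 2.12 ± 0.21, IER5 one across the stop codon at 1.60 ± 0.06 and JUN at 1.39 ± 0.02. Transcripts long described as m6A-modified, some of which are also in other lists, had 6 of 16 (adjusted p = 0.061, Fisher's exact test), with HIF1A at 2.30 ± 0.70 (intronic). Invasion and metastasis genes had 6 of 28 (adjusted p = 0.50, Fisher's exact test). The peak of MMP14, a membrane-bound matrix metalloproteinase, was coding and strong, on chromosome 14 at 22845707–22845887, with IP RPKM of 134 and 99.8 against input RPKM of 25.5 and 20.9 and a log2 fold of 2.28 ± 0.10. EGFR (1.92 ± 0.03, intronic), ITGA5 (1.40 ± 0.03) and MET (1.36 ± 0.11) also had shared peaks.

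Luminal and epithelial markers had 3 of 25 (adjusted p = 0.79, Fisher's exact test), namely CLDN7 (1.79 ± 0.06, intronic), SPDEF (1.35 ± 0.01) and ESRP2 (1.31 ± 0.11). Of the blood and endothelial cell markers 1 of 22 had a shared peak (adjusted p = 0.29, Fisher's exact test), CD14 at 1.10 ± 0.05 with IP RPKM of 6.54 and 3.05. With replicate 1 alone that list was below other genes (adjusted p = 0.047, Fisher's exact test). Glycolysis had 1 of 21, PFKP at 1.22 ± 0.19, and cell cycle genes 2 of 31 (adjusted p = 0.29 for each list, Fisher's exact test), CCND3 at 1.74 ± 0.16 and RB1 at 1.05 ± 0.01, both intronic. The glycolysis odds ratio of 0.26 became 0.32 without replicate 1 and 0.90 without replicate 2. That of cell cycle genes, 0.35, became 0.58 and 0.43, and none of these passed the threshold.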

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

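The test for peaks on the opposite strand was chosen only after its result had been seen; the other tests in this part were set before.

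Peaks outside the sense strand of annotated genes entered the shares and correlations over whole lists above, but not the gene lists or transcript positions. They recurred: 212 antisense and 308 intergenic peaks were shared by both replicates. Their median log2 folds were 1.40 and 1.37, with a median IP RPKM in replicate 1 of 8.99 and 8.69. Incomplete strand selection in the library could leave a second peak on the sense strand at the same place. Such an overlapping peak was found for 0.186% (0.00471–1.03) of the replicate 1 antisense peaks. Overlaps across strands were similarly rare among the intergenic peaks of that replicate (0.227%). The peak caller is not known and may keep a single strand per place, so the test cannot decide on incomplete strand selection. Transcription past the end of annotated genes is a candidate explanation for a part of the intergenic peaks, since of those 183 in replicate 1 that lay within 10 kb of a gene on the same strand, among the 6904 genes whose strand was known from a sense peak of their own, 74.3% (67.4–80.5) lay beyond its downstream end. The remaining 699 had none of these genes that near, but other annotated genes, whose strand was not used here, can lie close to them. Unannotated transcripts stay open, and no explanation from the study's groups was tested.

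Intronic peaks were shared less often than exonic ones, and lower depth may account for a part of that. The crude odds ratio of 3.76 (exonic over intronic, replicate 1) fell to 1.82 (1.65–2.01) within 4 classes of IP value. These classes are wide: the deepest ran from 157 to 37394 for exonic peaks and from 157 to 1356 for intronic ones. Differences in depth inside a class were left in, so the test cannot say whether depth accounts for the whole difference. Calls spread evenly over a gene would seldom recur at one place. Of the intronic replicate 2 peaks, 36.9% overlapped a replicate 1 peak, against at most 2.96% in 100 such placements within their genes. Random calls confined to the covered stretches of introns would also recur more often than these placements, so the test does not exclude them. Sites that recur in both libraries for a reason other than m6A, such as sequence-dependent antibody binding, stay open, and so does a lower precision of calls in weakly covered introns. No biological explanation was tested, since the design has no group that bears on it.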

How the results depend on the processing

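Settings limited to exonic or intronic peaks, an IP value of at least 100, the pseudocount of 0.1 RPKM and the minimum of 10% on each side of the stop codon were chosen after seeing the data; the others were set before. No paired analysis was possible because each list holds only peaks with a log2 fold of at least 1 of its IP over its own input, which fixes the outcome of a paired test over shared peaks; the folds are already paired within a list, and the p-values per peak are the authors'. Leaving out a replicate gives no value for sharing or correlation, which need both. The DRACH motif alternatives and the windows of 100 and 400 bases around the stop codon were not run. Gene lists at a fold of at least 4 gave no usable value: 58 protein-coding genes had such a shared peak, at most 0.228 members of a list were expected, and EGR1 and MMP14 were the members found. Sharing was low among peaks of low IP value, and the part that depth has in this was not separated from peak length and expression. Where no cause is given below, the cause was not tested.

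A p-value of at most 0.001 left 7110 and 7073 peaks, and a fold of at least 4 left 458 and 552. The share of replicate 1 peaks found in replicate 2 was 45.8% with reciprocal overlap, 58.1% at p of at most 0.001, 17.2% at a fold of at least 4, 65.2% for exonic and 33.1% for intronic peaks compared within their class, 75.2% at an IP value of at least 100, and 72.7% by gene; from replicate 2 it was 51.1%. The correlation of folds was 0.527 with reciprocal overlap, 0.584 at p of at most 0.001, 0.614 with the pseudocount of 0.1 RPKM and 0.624 at an IP value of at least 100. Minus log10 p in place of the fold correlated at 0.967. A p-value depends on depth as well as on the fold, so that r does not measure agreement of the enrichment alone. Peaks across the stop codon were 22.9% with at least 10% on each side and 25.9% to 27.8% in each replicate alone. At a fold of at least 4, which left 69 peaks, those mainly in the 3′ UTR were 37.7% (26.3–50.2), an interval that includes the main value of 30.5%. Those across the stop codon were 29.0% (18.7–41.2).

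With genes that have a peak in either list as background, which leaves fewer genes, odds ratios moved toward 1 in all 8 called lists, to 3.28 (m6A writers), 2.06 (SLIT-ROBO and mesenchymal genes), 3.38 (axon guidance), 2.35 (PI3K-AKT and MEK-ERK), 2.72 (chromatin regulators), 0.748 (ribosomal proteins) and 0.374 (respiratory chain), none past the threshold. They were 0.936 for erasers and readers and for invasion genes, which turned direction. This background asks a different question, namely how often genes with a peak had a shared one. Against span-matched lists the ratio of observed to matched members was 1.67 (SLIT-ROBO), 0.588 (ribosomal) and 0.306 (respiratory), no longer past the threshold, and 3.65 for immediate early genes, now past it. With exonic peaks alone immediate early genes (3.23) and cell cycle genes (0, none of 31 members) passed. In each replicate alone, odds ratios ranged from 1.83 to 4.72 for erasers and readers (past the threshold in replicate 2), from 0.137 to 0.473 for blood and endothelial markers (past it in replicate 1), from 4.03 to 9.01 for m6A writers, from 16.1 to 19.1 for chromatin regulators and from 0.216 to 0.287 for respiratory chain subunits (all on the side of the threshold they had), and from 1.35 to 1.41 for luminal markers, above 1 where the shared peaks gave 0.700. Of 102 gene list values under these alternatives, 82 kept their direction and their side of the threshold.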

Other observations

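For zinc finger genes, the tests of gene span and of chromosome location were set before their results were seen. The setting of exonic peaks alone was chosen after seeing the data, and so were the genes named in this part.

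Zinc finger genes with symbols starting in ZNF, many of which encode transcriptional repressors, carried m6A peaks more often than other genes. A shared peak was found in 188 of 517 (36.4%, 32.2–40.7) against 15.8% of the other protein-coding genes (odds ratio 3.05, Fisher's exact test, two-sided, p = 4.1e-29). With exonic peaks alone the shares were 31.9% and 12.3%. Gene span is one candidate explanation, but random lists matched on span had a mean of 16.2%. Location on chromosome 19, where many of these genes cluster, is another, and off that chromosome the odds ratio was 2.99 (2.33–3.86). Neither accounts for the whole pattern; exon length, expression and reads shared between near-identical family members may each contribute and were not tested, so m6A on this family remains a hypothesis.

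Long noncoding RNAs held 389 of the shared pairs in annotated genes, against 4389 in protein-coding genes. MALAT1, NEAT1 and MYC, which are among the transcripts long described as m6A-modified, had no peak in either list used here, and SON had 1 in replicate 1 alone. The deepest peaks were mitochondrial: MT-ND5 had an IP RPKM of 838 and 841 against input RPKM of 412 and 375, and MT-ND2 1113 and 1121 against 544 and 497. Their log2 folds, 1.02 to 1.17, were near the lower limit of the lists.

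TGFB1 had 7 shared peaks, of which 1 was exonic. Its intronic peak at 41331640–41332005 on chromosome 19 (GRCh38) had an IP RPKM of 53.6 and 51.8 in the 2 replicates, close to those of the exonic peak at 41353190–41353905 with 51.2 and 46.3. AXL, a receptor tyrosine kinase in the mesenchymal list, had 3 shared peaks, none of them exonic.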
